A study of Mus musculus with 6 samples.

How the data were processed

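Total RNA from OP9 cells, a mouse bone marrow stromal line used to support lymphoid cell culture, was measured on 6 Affymetrix Mouse Exon 1.0 ST arrays. The cells carried stably integrated lentiviral hairpins of the pLKO.1-puro type. Per the labels, 3 arrays held RNA from cells with a scrambled control hairpin (control shRNA) and 3 held RNA from cells with a hairpin against Smoothened (Smo shRNA), and the RNA was isolated in triplicate from each stable line. Nothing in the labels says that the triplicates came from separate transductions, so p-values measure only the spread between RNA samples of a line. A difference between the lines that has another origin than the hairpin is part of the same comparison. The number of hairpin sequences and the scan dates are not given in the sources used here.

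The deposited table holds 1256831 exon probe sets as log2 values made by the authors. That the scale is log2 was read from the values, which ran from 0 to 15.14, near the top of a 16-bit scanner. The array medians lay between 6.56 and 6.59 and the quartiles differed as little, so the values look normalized between arrays. The summary, background and normalization methods are not given in the sources used here. In 20744 rows (1.65%) every array read exactly 0. None of these rows was assigned to a gene, and they were treated as carrying no measurement. No 2 arrays shared more than 0.0233% of their values exactly, counted over rows different from 0.

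Gene names came from the platform annotation supplied with the series. In it, 318760 probe sets had 1 gene symbol, 6684 had several and were left out of gene values, and 931387 had none and were unnamed here. Of the 22296 symbols, 18006 were current in the mouse RefSeq gene table of assembly GRCm38.p6, 3993 were updated through a synonym belonging to 1 gene, and 297 kept the older name. The same table placed genes on chromosomes. None of its coordinates are printed, because the build of the array annotation is not given in the sources used here.

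Probe sets with a mean over the 6 arrays at or above the median of all probe sets (6.56) were kept, which left 245574. Genes with 3 or more kept probe sets were joined per array by Tukey median polish, giving 16923 genes with a median of 11 probe sets each. Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a variance trend and no replicate block, a two-sided test and Benjamini-Hochberg adjustment with a threshold of 0.05. Differences are Smo shRNA minus control shRNA on the log2 scale, and SE is the moderated standard error. Folds from hybridization intensities understate changes of dim genes, and no detection call per probe set was used. The number of arrays limits the precision.

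A total of 25 gene lists were fixed before the data were examined and tested with camera from limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. One alias in the Hedgehog pathway list, which the RefSeq table assigns to Axin1, was removed after the data were seen because Stk36 had been meant. For each list the members past the threshold were counted over all genes and adjusted over the list alone. Camera was repeated with a correlation estimated from the arrays, and fry, which tests a list against no change and not against other genes, was run as well. Exon usage was tested with limma's diffSplice on the kept probe sets, with a Simes p per gene. Members of the lists that did not reach 3 kept probe sets with a single gene name were not analysed here.

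The genes named in the text follow a rule fixed before the data were examined. It takes Smo, the tested members of the Hedgehog pathway, Hedgehog target and stromal support lists with at most 10 given in full, and the 12 largest log2 differences in each direction. Those 24 genes had to pass the threshold with no overlap between the 3 and 3 arrays, and gene models and small RNA genes were passed over. The rule also takes up to 4 members with the smallest adjusted p for every other list that was called, up to 2 for every list that was not, and the 5 genes with the smallest Simes p for exon usage. The symbol C3 has the form of a gene model under the rule and was named through the inflammatory list.

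The calculation was tested on simulated data with the spread of these arrays and 16923 genes. Few of the simulated genes were changed, which makes the adjusted threshold stricter than where many genes change. The shares below therefore do not give the recovery in the real comparison. In the simulated comparison of Smo shRNA with control shRNA, genes changed 1.1, 1.25, 1.5 and 2-fold were recovered in 2, 30, 86 and 98% of cases (50 genes each), and 4 of 16543 unchanged genes were called. For exon usage, diffSplice recovered 50, 94 and 100% of genes with 1 probe set changed 1.5, 2 and 4-fold, but it also called 835 of 16773 genes with no usage change. A splicing index, the probe set value minus the gene value with its own moderated variance, was therefore added after seeing this. It called 0 genes without a usage change and recovered 0, 46 and 80% at the same sizes. Simulated genes changed by at most 2-fold, and all probe sets of a changed gene were shifted alike. False calls of the index in genes with larger changes or unequal probe set responses were therefore not measured. A shifted list was found at both correlation settings, and 0 of 24 random lists were called. The simulated genes varied independently of each other. The simulation could therefore not show how often lists of correlated genes are called falsely.

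The alternatives planned before the data were examined were leaving out each array in turn, a replicate block, quantile normalization, centring of each array, no filter or a stricter one (75th percentile) on dim probe sets, the mean in place of median polish, at least 5 probe sets per gene, eBayes without the trend or with robust settings, array weights, stricter thresholds, the estimated correlation and fry. Chosen after seeing the data were the splicing index, leaving out genes of chromosome 12 or of chromosomes 11 and 12, and keeping Axin1 in the Hedgehog pathway list or leaving Smo out of it.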

Results

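The series measured gene expression in 2 stable lines of OP9 cells, one with a scrambled control hairpin and one with a hairpin against Smoothened (Smo), the G protein-coupled receptor-like protein through which Hedgehog ligands signal. Each line was sampled 3 times, giving 3 control shRNA and 3 Smo shRNA arrays. The comparison asks what lowering Smo changes in a stromal cell that supports early B cells. Over 16923 tested genes, values of arrays from the same line correlated at 0.996 to 0.998 across genes, and values of arrays from different lines at 0.979 to 0.981, where genes are not independent replicates. The first principal component, which separated the lines, held 80.5% of the variance. The median SD of a gene within a line was 0.07.

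Smo itself, the target of the hairpin, was 1.84-fold lower in Smo shRNA cells. Its level was 12.25 ± 0.03 (SD, n = 3) in control cells and 11.38 ± 0.06 (SD, n = 3) in Smo shRNA cells, a log2 difference of -0.88 (SE 0.04, limma adjusted p = 4.53e-10). All 26 Smo probe sets were lower in Smo shRNA cells, and 24 of them passed the threshold on their own. Their differences ran from -1.49 to -0.07, and the 2 that missed the threshold were the dimmest. The brightest Smo probe sets also changed less than most, by -0.72, -0.54 and -0.35, so the size of the knockdown is uncertain.

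Among the other genes of the Hedgehog pathway, Gas1 and Ptch1 fell while Hhip rose. The pathway raises some of its target genes and lowers others, so a fall alone does not show lowered signalling. Gas1, a co-receptor for Hedgehog ligands, fell by 0.93 on the log2 scale (SE 0.04, adjusted p = 9e-10), from 11.48 ± 0.03 (SD, n = 3) to 10.56 ± 0.05 (SD, n = 3). Ptch1, the Hedgehog receptor and a target gene of the pathway, fell by 0.39 (SE 0.05, adjusted p = 2.2e-05), and the co-receptor Boc fell by 0.35 (SE 0.04, adjusted p = 2.13e-06). Hhip, a Hedgehog-binding protein that is also a target gene, was 2.07-fold higher, at 9.68 ± 0.11 (SD, n = 3) in control cells and 10.73 ± 0.04 (SD, n = 3) in Smo shRNA cells (log2 difference 1.05, SE 0.06, adjusted p = 5.64e-09). All 20 Hhip probe sets were higher and 19 passed on their own, and all 28 Ptch1 probe sets were lower and 21 passed.

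Gli1, a transcription factor and target gene of the pathway, was 0.25 higher (SE 0.07, adjusted p = 0.0113) at a low level, 8.31 ± 0.11 (SD, n = 3) against 8.57 ± 0.01 (SD, n = 3). Of its 20 probe sets, 5 were higher and 1 lower at the threshold. The Gli1 call was lost without control replicate 3 (0.14), without any of the 3 Smo shRNA replicates, and with the stricter filter, and its adjusted p ran from 0.002 to 0.215 over all 16 alternatives. Stk36 fell by 0.43 (SE 0.08, adjusted p = 0.000296) and Gli3 by 0.19 (SE 0.05, adjusted p = 0.00517), while Gli2 (0.00, adjusted p = 0.973) and Sufu (-0.02, adjusted p = 0.769) did not pass. The Gli3 call was lost in 4 of the 6 fits that left out an array.

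**Figure D1:**
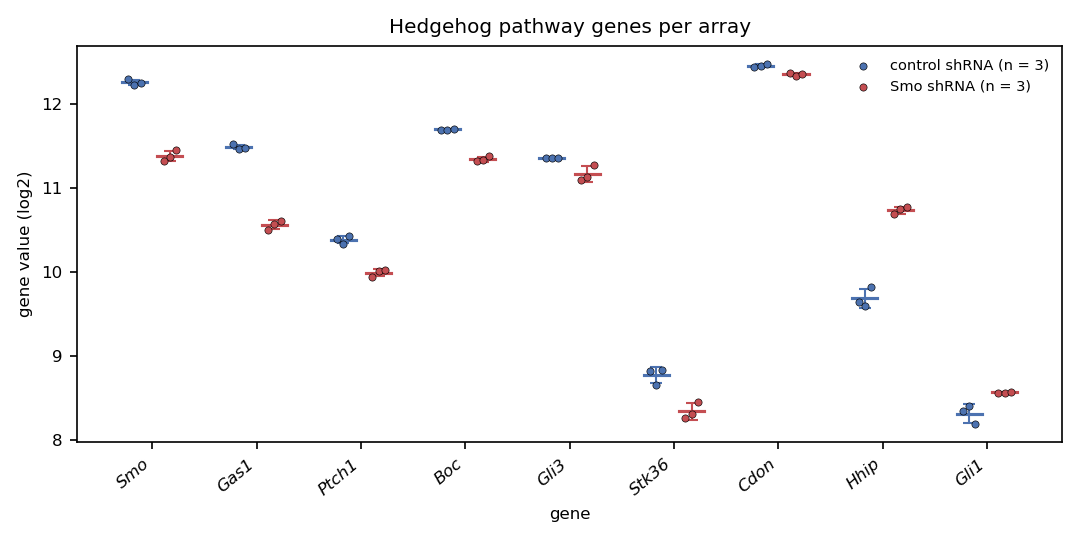
Gene values (log2, vertical axis) of 9 Hedgehog pathway genes (horizontal axis) in 3 control shRNA and 3 Smo shRNA arrays. Points are arrays, short lines are group means and bars are SD. Smo, Gas1, Ptch1, Boc, Gli3, Stk36 and Cdon lie lower in Smo shRNA cells, and Hhip and Gli1 lie higher.

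Of 27 tested Hedgehog pathway components, Smo included, 10 fell, 3 rose and 14 did not pass (7 to 11 lower and 2 to 3 higher without 1 array), with the same counts adjusted over the list alone. The list was lower as a whole by camera (adjusted p = 0.0256), a call that was lost with an estimated correlation (adjusted p = 0.336 with an estimated correlation), without genes of chromosomes 11 and 12 (adjusted p = 0.0545) and without Smo. With Smo left out, a test added after seeing the data, 9 of 26 fell, 3 rose and the list was not called (adjusted p = 0.0564). The call was kept in 16 of 19 alternatives, of which fry (adjusted p = 0.00149) tests the list against no change and not against other genes. This list was not divided by whether a member promotes or restrains the pathway, so its direction does not measure pathway output. Of 30 tested Hedgehog target genes, 10 fell and 8 rose (10 and 9 adjusted over the list alone). The list as a whole was not called (camera adjusted p = 0.628). It does not separate targets that the pathway raises from those that it lowers. Neither the counts nor this test in 1 direction therefore measures the output of the pathway. Leaving out 1 array gave 8 to 10 lower and 6 to 7 higher targets, and the call of Ccnd1 was lost in 6 of 6 such fits, that of Bmi1 in 4 and that of Cdon in 3. Besides Gas1 and Ptch1, the targets that fell included Bmp4, a bone morphogenetic protein (-0.39, SE 0.04, adjusted p = 2.12e-06), and the survival factor Bcl2 (-0.38, SE 0.07, adjusted p = 0.00041). Those that rose included the transcription factors Osr2 (0.50, SE 0.07, adjusted p = 2.59e-05) and Nr2f1 (0.48, SE 0.07, adjusted p = 3.65e-05).

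Of 27 tested genes by which stromal cells support lymphoid and myeloid progenitors, 12 fell and 2 rose in Smo shRNA cells (11 to 13 and 1 to 2 without 1 array). Il7, the cytokine that early B cells depend on, was 2.29-fold lower, at 9.37 ± 0.14 (SD, n = 3) in control cells and 8.18 ± 0.22 (SD, n = 3) in Smo shRNA cells (log2 difference -1.19, SE 0.10, adjusted p = 2.74e-07). Cxcl12, the chemokine that retains B cell precursors in marrow, was 1.65-fold lower (-0.72, SE 0.04, adjusted p = 4.91e-09), and Kitl, which encodes stem cell factor, was 1.61-fold lower (-0.69, SE 0.04, adjusted p = 3.03e-09). The largest change in the list was that of the growth factor Ptn, which was 3.29-fold lower (-1.72, SE 0.07, adjusted p = 3.25e-10). Angpt1, a ligand of the Tie2 receptor, was 2.14-fold lower (-1.10, SE 0.04, adjusted p = 2.28e-11).

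Igf1 and the adhesion molecule Cdh11 each fell by 1.00 on the log2 scale, and the transcription factor Ebf3 was 1.73-fold lower (adjusted p at most 4.29e-09 for the 3 genes). Tslp, a cytokine related to Il7, rose by 0.47 (SE 0.09, adjusted p = 0.000754), or by 0.30 without the filter on dim probe sets. Csf1 (0.01, adjusted p = 0.787) and Vcam1 (-0.08, adjusted p = 0.353) were among the 13 members that did not pass, and the counts were the same adjusted over the list alone. The list was lower as a whole by camera (adjusted p = 0.000238), and this call was lost with the correlation estimated from the arrays (adjusted p = 0.336 with an estimated correlation).

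**Figure D2:**
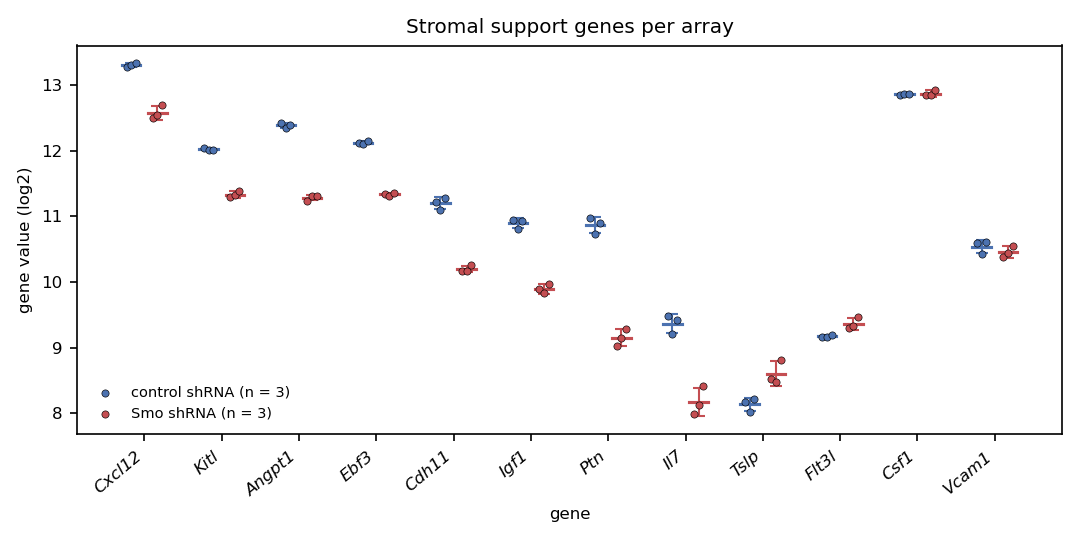
Gene values (log2, vertical axis) of 12 stromal support genes (horizontal axis) in 3 control shRNA and 3 Smo shRNA arrays, with group means as short lines and SD as bars. From Cxcl12 to Il7 the arrays of the Smo shRNA line lie below those of the control line, Tslp and Flt3l lie above (the Flt3l call was lost in each fit without 1 array), and Csf1 and Vcam1 overlap.

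Across all genes, 6549 of 16923 (38.7%) passed the threshold, 3595 higher and 2954 lower in Smo shRNA cells, most by small amounts. The median size of a called difference was 0.30, or 1.23-fold. Changes of 2-fold or more were rarer and mostly downward, with 68 genes higher and 198 lower. At 1.5-fold or more, 461 genes were higher and 565 lower.

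Colec10, a gene for a secreted collectin, showed the largest decrease and was 10.2-fold lower, at 10.99 ± 0.04 (SD, n = 3) in control cells and 7.64 ± 0.12 (SD, n = 3) in Smo shRNA cells (log2 difference -3.35, SE 0.07, adjusted p = 2.27e-13). Prkg1, a cGMP-dependent protein kinase, was 9.13-fold lower, and Postn, the matrix protein periostin, was 7.80-fold lower, falling from 12.78 ± 0.02 (SD, n = 3) to 9.81 ± 0.06 (SD, n = 3). Itga1, a collagen-binding integrin chain, was 5.48-fold lower, and the actin-associated genes Sorbs2 and Limch1 were 5.07-fold and 4.95-fold lower. Ppargc1a, a coactivator of mitochondrial genes, was 5.43-fold lower, and the imprinted RNA H19 was 5.16-fold lower. The retinaldehyde dehydrogenase Aldh1a1 and its relative Aldh1a7 were 5.46-fold and 6.74-fold lower, Lyz2, which encodes a lysozyme, 5.63-fold and Trim30d 5.41-fold. All 12 had an adjusted p of 4.27e-09 or less. The log2 difference of Aldh1a1 (-2.45) was -1.38 with the stricter filter on dim probe sets, so its place among the 12 is uncertain.

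The largest increases were in Mcpt8, a protease gene, and in Prr32, which were 5.07-fold and 4.11-fold higher. Mcpt8 went from 8.29 ± 0.08 to 10.64 ± 0.10 (SD, n = 3, log2 difference 2.34, SE 0.07, adjusted p = 6.44e-12). Gprc5a, an orphan receptor, was 3.93-fold higher, Lrrn3 3.56-fold, the lysosomal protease gene Ctsc 3.21-fold, Il13ra1, a chain of the interleukin 13 receptor, 3.16-fold and F5, coagulation factor V, 3.16-fold. Adcy3, an adenylyl cyclase, was 3.12-fold higher, Gstk1 2.95-fold, the phosphatase gene Dusp3 2.83-fold, Cd209c 2.77-fold and Ereg, a ligand of the EGF receptor, 2.74-fold. All 12 had an adjusted p of 1.24e-07 or less. The log2 difference of Cd209c (1.47) was 0.47 without Smo shRNA replicate 3, 0.96 without Smo shRNA replicate 1 and 2.10 without control replicate 3. The filter on dim probe sets was applied anew in each of these fits. The SD of Cd209c was only 0.12 in control cells and 0.17 in Smo shRNA cells (n = 3 each). These moves therefore cannot be put down to single arrays. The Cd209c difference was 0.88 without the filter on dim probe sets and 0.56 with the stricter filter. The log2 difference of F5 (1.66) was 0.46 with the stricter filter, so the places of F5 and Cd209c among the 12 are uncertain. Aldh1a1, Aldh1a7, Lyz2, Trim30d and Cd209c have close paralogs, and their probe sets can carry signal of a relative. The control means of Cd209c (6.53), F5 (6.80) and Prr32 (6.86) and the Smo shRNA means of Lyz2 (6.64), Prkg1 (6.68) and Aldh1a1 (6.84) lay near the median of all probe sets (6.56), where a fold is least certain.

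Most tested genes of DNA replication were higher in Smo shRNA cells. Mcm2 and Mcm5, subunits of the replicative helicase, were 1.93-fold higher (0.95, SE 0.04, adjusted p = 2.3e-10) and 1.61-fold higher (0.69, SE 0.04, adjusted p = 2.97e-09). Cdt1, which loads that helicase, was 1.62-fold higher, and Uhrf1, which maintains DNA methylation at replication, was 1.46-fold higher. Of 33 S-phase genes, 30 rose, 0 fell and 3 did not pass, with the same counts adjusted over the list alone, and the median difference was 0.44 (camera adjusted p = 4.17e-14, adjusted p = 0.336 with an estimated correlation). Genes of mitosis had a median difference of 0.22, and the 2 lists were not tested against each other. Of 37, 29 rose, 2 fell and 6 did not pass, or 31, 3 and 3 adjusted over the list alone. Leaving out 1 array gave 23 to 26 higher and 1 to 2 lower mitosis genes. The camera adjusted p of this list was 5.3e-08, and 0.336 with an estimated correlation. The mitotic kinase gene Bub1 was 1.47-fold higher (0.56, SE 0.04, adjusted p = 3.67e-08), the transcription factor gene Foxm1 1.33-fold, and Kif11 and Ect2 rose by 0.33 and 0.32 on the log2 scale. The 2 that fell were Ckap2 (-0.24) and Kif20a (-0.11), which code for a spindle protein and a kinesin and were named after their values were seen.

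Adipocyte and smooth muscle genes changed mainly downward among those that passed. The adipocyte genes Adipoq, which encodes adiponectin, Cd36, a fatty acid transporter, and Lpl, lipoprotein lipase, were 3.99-fold (-2.00, SE 0.11, adjusted p = 3.06e-09), 2.89-fold (-1.53, SE 0.06, adjusted p = 6.46e-11) and 2.52-fold lower (-1.33, SE 0.05, adjusted p = 6.07e-11). Of 34 adipocyte genes, 14 fell and 4 rose (15 and 4 adjusted over the list alone, camera adjusted p = 0.00386, adjusted p = 0.336 with an estimated correlation). Among smooth muscle and pericyte genes, Myl9 was 3.69-fold lower (-1.88, SE 0.06, adjusted p = 9.7e-12), Actg2 2.60-fold lower and Acta2, smooth muscle actin, 1.68-fold lower. Mcam, a surface molecule of pericytes, was instead 2.46-fold higher (1.30, SE 0.06, adjusted p = 3.13e-10). In that list of 19 genes, 10 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00186, adjusted p = 0.336 with an estimated correlation).

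Extracellular matrix genes moved both ways, with 19 of 43 lower and 8 higher (18 to 19 and 5 to 7 without 1 array, 20 and 9 adjusted over the list alone, camera adjusted p = 0.008, adjusted p = 0.336 with an estimated correlation). Fbln5, an elastic fibre protein, was 2.99-fold lower, the collagen gene Col8a1 2.23-fold, the aggrecanase gene Adamts5 1.73-fold and thrombospondin 1 (Thbs1) 1.61-fold. Osteoblast genes fell in 9 of 21 cases and rose in 4, among them Postn and Dlx5 (-0.82, SE 0.06, adjusted p = 3.01e-08) on the lower side, and the list missed the threshold (camera adjusted p = 0.0564). The osteoblast list was called with the stricter filter (adjusted p = 0.0234), the mean of probe sets (0.0483) and at least 5 probe sets (0.0275). Cartilage genes fell in 4 of 16 cases and rose in 0 (camera adjusted p = 0.0849), with Col10a1 2.39-fold and Col2a1 1.33-fold lower. For the osteoblast and cartilage lists the counts adjusted over the list alone were the same.

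Single genes of signalling pathways changed strongly in lists that were not called as a whole. In the Notch list, the target Hey1 was 3.07-fold lower (-1.62, SE 0.07, adjusted p = 3.36e-10) and Maml2 1.66-fold lower, while 7 of 27 members rose and 6 fell (camera adjusted p = 0.858). In the Wnt list, Rspo2, an enhancer of Wnt signalling, and Sfrp1, a Wnt antagonist, were 3.43-fold and 2.64-fold lower, with 8 of 35 members lower and 4 higher (6 to 7 and 2 to 4 without 1 array, camera adjusted p = 0.102). In the BMP and TGF-beta list, Ccn2 and Ltbp1 were 1.54-fold and 1.37-fold higher, with 10 of 27 members lower and 6 higher (9 to 10 and 4 to 5 without 1 array, camera adjusted p = 0.0742). The BMP and TGF-beta list was called without Smo shRNA replicate 1 (adjusted p = 0.045) and with the mean of probe sets (0.0467). The counts of these 3 lists were the same adjusted over the list alone. Of 20 mesenchymal stromal markers, 6 fell and 3 rose (4 to 6 and 2 to 3 without 1 array, 6 and 4 adjusted over the list alone, camera adjusted p = 0.628), Mcam and Twist2 (1.42-fold) being higher.

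Among inflammatory and interferon genes, 10 of 27 and 11 of 34 fell in Smo shRNA cells. Leaving out 1 array gave 9 to 12 and 7 to 10 lower, and 0 to 2 higher in each list. C3, the central complement component, was 7.35-fold lower (11.31 ± 0.09 to 8.44 ± 0.10, SD, n = 3, log2 difference -2.88, SE 0.06, adjusted p = 5.54e-13). The chemokine genes Cxcl5, Ccl2 and Ccl7 were 1.84-fold, 1.51-fold and 1.39-fold lower, the log2 difference of Ccl2 being -0.60, or -0.94 with the mean of probe sets. In the inflammatory list 1 gene rose and 16 did not pass (11 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00187, adjusted p = 0.336 with an estimated correlation). Among interferon-stimulated genes, Ifi44 was 3.16-fold lower (-1.66, SE 0.11, adjusted p = 2.38e-08), Bst2, which tethers virions, 1.57-fold, the peptide transporter gene Tap1 1.43-fold, and Ddx58, which encodes the RNA sensor RIG-I, 1.38-fold.

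In the interferon list 2 genes rose and 21 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0497, adjusted p = 0.608 with an estimated correlation). Of 25 p53 target genes, 10 fell and 4 rose (8 to 10 and 2 to 4 without 1 array), with the same counts adjusted over the list alone (camera adjusted p = 0.0437, adjusted p = 0.645 with an estimated correlation). Trp53inp1, a stress-induced p53 target, was 2.80-fold lower (-1.48, SE 0.06, adjusted p = 3.35e-10), the death receptor gene Fas 2.20-fold, the antiproliferative gene Btg2 1.95-fold and Phlda3 1.28-fold. The interferon call was lost without control replicate 2 or 3 or Smo shRNA replicate 1, and the p53 call in every fit without 1 array except that without Smo shRNA replicate 3. Both were also lost without genes of chromosome 12 (adjusted p = 0.0501 for each), and the interferon call with Smo left out of the Hedgehog list (adjusted p = 0.0553), through the adjustment over lists. Without genes of chromosomes 11 and 12 the interferon list was called (adjusted p = 0.0225) and the p53 list was not (adjusted p = 0.101). Other losses were those of the interferon call with quantile normalization (adjusted p = 0.0578), at least 5 probe sets (0.0708) and the stricter filter (0.0801), and of the p53 call with the stricter filter (0.0628). Each call was kept in 10 of 19 alternatives, among them fry, which tests a list against no change (adjusted p = 0.0215 for interferon-stimulated genes and 0.0148 for p53 target genes).

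Genes of the unfolded protein and amino acid stress list changed in both directions, 14 of 29 higher and 11 lower (camera adjusted p = 0.401). Slc7a11, the cystine transporter, was 2.63-fold higher (1.40, SE 0.06, adjusted p = 2.6e-10), and Shmt2, a mitochondrial serine hydroxymethyltransferase, 1.51-fold higher. Of 20 cholesterol synthesis genes 5 were higher and 5 lower (2 to 3 and 4 to 5 without 1 array, camera adjusted p = 0.628), with Dhcr7 1.40-fold and Lss 1.34-fold higher. Of 35 genes of the primary cilium, the organelle in which Smo signals, 13 fell and 5 rose, and the list missed the threshold (camera adjusted p = 0.0564). Leaving out 1 array gave 8 to 13 lower and 2 to 4 higher, with an adjusted p from 0.0122 to 0.218 for the primary cilium list, which was called in 2 of the 6 fits. It was also called without the filter on dim probe sets (adjusted p = 0.0374). Its transport genes Ift52 and Ift20 were 1.38-fold and 1.26-fold lower. The counts of these 3 lists were the same adjusted over the list alone.

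The lists of markers of other cell types had median levels from 7.81 to 8.34, below the level of the median tested gene (9.20). Of 24 haematopoietic and B-lineage markers, 1 rose and 2 fell (camera adjusted p = 0.628). The counts were 1 and 1 adjusted over the list alone, and 1 and 1 to 2 without 1 array. Lyz2 fell from 9.13 ± 0.27 to 6.64 ± 0.29 (SD, n = 3), while Cd68, a lysosomal protein abundant in macrophages, rose from 8.54 ± 0.08 to 9.01 ± 0.12 (SD, n = 3). Other macrophage genes named after their values were seen, Csf1r (-0.00, adjusted p = 0.973), Adgre1 (-0.06, adjusted p = 0.66) and Itgam (-0.01, adjusted p = 0.973), did not pass. No member of the endothelial (17 genes, camera adjusted p = 0.89) or epithelial list (16 genes, camera adjusted p = 0.89) passed, the smallest adjusted p being those of Sox17 (-0.10, adjusted p = 0.297), Robo4 (-0.12, adjusted p = 0.353), Cldn3 (0.11, adjusted p = 0.249) and Krt8 (0.09, adjusted p = 0.374).

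Of 18 skeletal muscle markers, Tnnt3 (-0.22, adjusted p = 0.0179) and Acta1 (-0.17, adjusted p = 0.0495) fell over all genes, and 0 passed adjusted over the list alone (camera adjusted p = 0.766). Leaving out 1 array ended the call of Tnnt3 in 4 of 6 fits and that of Acta1 in 5, and the Tnnt3 difference was -0.40 with the mean of probe sets. Of 15 neural and glial markers, Map2, a microtubule-associated protein, fell by 0.95 (SE 0.06, adjusted p = 1.33e-08) and the tubulin gene Tubb3 rose by 0.25 (SE 0.07, adjusted p = 0.00822), a call that was lost in 4 of the 6 fits without 1 array (1 and 1 adjusted over the list alone, camera adjusted p = 0.766). The sign of the median, the mean and the test differed in the Notch, mesenchymal marker, cholesterol, endothelial, epithelial, skeletal muscle and neural lists, none of which was called.

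**Figure D3:**
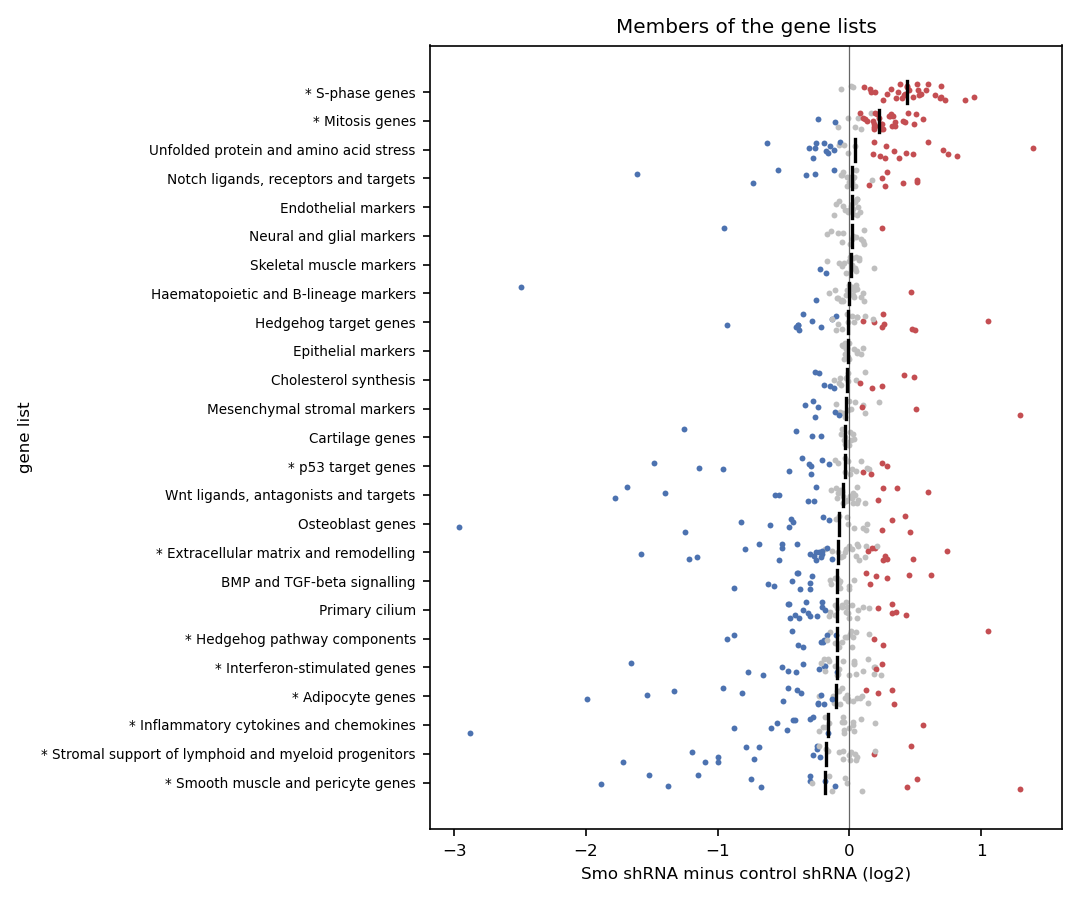
Log2 difference between Smo shRNA and control shRNA cells (horizontal axis) of each tested member of the 25 gene lists (vertical axis, ordered by median). Red and blue points passed the threshold as higher and lower, grey points did not, black lines are list medians, and a star marks lists called by camera at the preset correlation. The S-phase and mitosis lists lie to the right, with medians of 0.44 and 0.22, and the smooth muscle and stromal support lists have the lowest medians, -0.18 each.

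In all, 10 of the 25 lists were called, 2 higher and 8 lower. With an estimated correlation 0 were called, where 2 lists had an unadjusted p under 0.05, those of inflammatory genes (0.0162) and S-phase genes (0.0378), while fry, which tests each list against no change, called 15. With Smo left out of the Hedgehog list 8 were called. Another division of the 6 arrays into 3 and 3 called 9 lists at the preset correlation.

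When genes were grouped by chromosome, a grouping chosen after the data were seen, those of chromosome 12 stood apart. Among the brighter genes, those with a mean at or above the median gene, the 268 on chromosome 12 had a median difference of 0.40, or 1.32-fold higher in Smo shRNA cells, and 84.7% of them were above 0. The 696 on chromosome 11 had a median of 0.12. Medians of the other chromosomes lay between -0.02 and 0.06. Lrrn3 and Adcy3 lie on chromosome 12 and Dusp3 on chromosome 11. Smo, Ptch1, Hhip and Gli1 lie on neither. Without genes of chromosome 12, 6243 genes passed, 3319 higher and 2924 lower, and the S-phase and stromal support lists kept their calls at the preset correlation (adjusted p = 8.65e-15 and 0.000332). Over all genes both were lost with an estimated one (adjusted p = 0.336 with an estimated correlation for each).

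**Figure D4:**
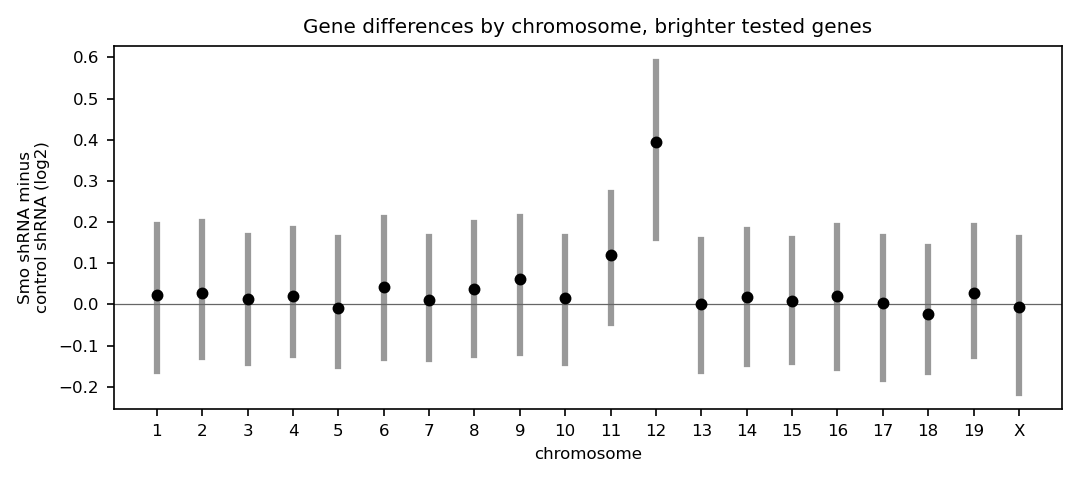
Log2 difference between Smo shRNA and control shRNA cells (vertical axis) for the brighter tested genes (mean at or above the median gene) on each chromosome (horizontal axis). Points are medians and bars run from the 25th to the 75th percentile of genes. Chromosome 12 has a median of 0.40, chromosome 11 of 0.12, and the others lie close to 0.

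Exon probe sets of a gene did not always change together. In Fbln2, a matrix protein of the fibulin family, 1 probe set was 1.30 lower in Smo shRNA cells (9.84 ± 0.06 to 8.54 ± 0.17, SD, n = 3) while the gene as a whole was 0.18 higher. In Pde10a, a cyclic nucleotide phosphodiesterase, 1 probe set was 2.70 higher and the gene 0.79 higher. In the transcription factor gene Ets1 the values were 2.82 and 0.35, and in Nsf, which acts in membrane fusion, 2.18 and 0.56. In C3, 1 probe set changed by -0.31 against -2.88 for the gene. Over all genes, diffSplice called 4795 of 16923, the 5 named genes having the smallest Simes p (adjusted p at most 2.38e-26). The splicing index, chosen after seeing the simulated data, called 713, of which 697 were shared and which included all 5 named genes (adjusted p from 0.00239 to 0.0354). The share called by diffSplice rose with the size of the gene's own change, from 15.3% of genes that changed by less than 0.1 to 90.6% of those that changed by 1 or more, and this test also made 835 calls among 16773 simulated genes with no usage change. The share called by the splicing index rose with the gene's own change as well, from 1.23% to 60.5% of the same genes.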

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

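The tests of chromosome 12 and the test on probe sets without a gene name were chosen after the result was seen. Probe sets assigned to no gene lie outside the comparison of genes, and among 378526 of them above the brightness filter, 837 were at least 2-fold higher in Smo shRNA cells than in control shRNA cells and 2185 at least 2-fold lower (limma adjusted p under the threshold). Probe set 5450176 went from 5.14 ± 0.48 to 9.51 ± 0.04 (SD, n = 3) and probe set 4902893 from 5.45 ± 0.13 to 9.02 ± 0.04 (SD, n = 3). Probe set 5213126 went from 11.31 ± 0.14 to 6.34 ± 0.22 (SD, n = 3) and probe set 4573329 from 10.68 ± 0.10 to 6.21 ± 0.37 (SD, n = 3). Which transcripts they measure was not analysed here.

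The 6 arrays can be divided into 3 and 3 in 10 ways, so the share of divisions with a result as large is never under 0.1. That is too few for a share under 0.05. Counting the real division, 1 of 10 reached its count in each case. The real division called 6549 genes and the highest other 0, the real one called 10 lists and the highest other 9, and the real one called 4795 genes for exon usage and the highest other 625. Every other division puts arrays of both lines in each group, so the difference between the lines adds to the spread within groups. The contrast of 6549 with 0 genes therefore decides nothing.

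Genes of chromosome 12 were higher in Smo shRNA cells, with a median of 0.40 over the brighter genes. Chance placement of regulated genes was argued against by shuffling genes over chromosomes, where a share of 1e-04, the smallest that 10000 shuffles can give, reached such a median. A bias with brightness was argued against as well, since genes of other chromosomes matched on brightness differed from those of chromosome 12 by 0.37 (bootstrap SD 0.03) over the brighter genes and by 0.22 over all genes. A candidate explanation is a difference in the copy number of chromosome 12 between the 2 lines, a gain in one or a loss in the other, and the lowest median among the 10 parts of its gene order was 0.24, the highest 0.56. It remains a hypothesis, since DNA was not analysed here, and an effect of the Smo hairpin on genes along the whole chromosome stays open as untested.

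Hhip and Gli1 were higher while Ptch1, a target gene of the same pathway, was lower. For Hhip, stray single probe sets were argued against, as a share of 0.95 of its probe sets were higher on their own. For Gli1 the share was 0.25, at the bound set beforehand, and with a level near 8.4 it cannot be told apart from stray single probe sets. The shift of chromosomes 11 and 12 does not carry the pair, as 0 of the 2 genes lie there. A response of Hhip to the lowered Smo, and a difference between the lines that arose apart from the hairpin, both stay open as untested.

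Exon usage calls were frequent both in genes that changed strongly and in genes that hardly changed. Among 1080 called genes that changed by 0.5 or more, the dimmest of 4 brightness classes of probe sets showed 0.948 (bootstrap SD 0.02) of the change of the third class, above the bound of 0.9 set beforehand for a damped response of dim probe sets. That bound left out the bright end, where the brightest class showed 0.894 (bootstrap SD 0.01) of it (medians 0.70, 0.76, 0.74 and 0.66 from dim to bright), so an unequal response stays open. Among 1185 called genes that changed by less than 0.1, the leading probe set deviated by a median of 0.61, but the bound set for it was wrong, since called genes and their leading probe sets are chosen for a large deviation, and the value decides nothing. Probe sets with a spread above that pooled over their gene stay open too, given the 835 calls among 16773 simulated genes without a usage change, as do alternative exons in Smo shRNA cells, for which no test of isoforms was made.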

How the results depend on the processing

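Chosen after seeing the data were the splicing index, the fits without chromosomes 11 and 12, and the Hedgehog pathway list with Axin1 kept or Smo left out. The Smo difference kept its direction and call in all 16 alternatives, from -0.91 to -0.84. Leaving out 1 array gave 4827 to 5574 genes changed (2685 to 2925 higher, 2089 to 2808 lower), 8 to 11 gene lists and 3553 to 5023 genes with exon usage calls. Quantile normalization gave 6744 genes changed, centring 6191, no filter 6394, the stricter filter 6395, the mean of probe sets 6465, at least 5 probe sets 6377, no variance trend 6006, robust settings 6555, array weights 8096 and an adjusted p under 0.01 5166. A log2 difference of 1 or more left 266 genes changed, 68 higher and 198 lower, by construction of the threshold. Without chromosome 12 there were 6243 and 8 lists, and without chromosomes 11 and 12 there were 5673 and 8 lists. In each of these fits the called genes shared with the first fit had the same sign. Camera with an estimated correlation called 0 gene lists, against 10 at the preset one, fry, which tests against no change, called 15 and the list with Axin1 left the count at 10, while the list without Smo gave 8. Exon usage calls fell from 4795 to 713 with the splicing index, and the cause was not tested beyond the simulated data. Over the alternatives, 2413 of 2503 values of single named genes stayed on the same side of the threshold. Of the others, 57 lost the call, 33 gained it and 0 changed direction where either fit passed. Genes that passed in neither fit counted as unchanged even where the sign differed, as for Gli2 (from -0.04 to 0.05). For single lists the numbers were 434 on the same side of the threshold, 28 lost, 13 gained and 0 with a direction changed past it. Directions of lists that were not called could differ, as for the mesenchymal marker list, lower by camera and higher by fry.

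With the replicate number as a block, 6954 genes changed (3806 higher, 3148 lower), 10 lists and 5407 genes for exon usage were called, and Smo differed by -0.88. Samples sharing a number had deviations from their group means that correlated across genes at 0.08, 0.10 and 0.39, not all over 0.1, and 4 of the 6 samples correlated best with their own number, so the numbers were not taken as pairs. No detection calls were used, and near the dim end of the scale, around 6.56, the arrays limit what can be called.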

Other observations

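The 6 lists below and their tests, and the genes named from them, were chosen after the data were seen. Genes of ribosome biogenesis rose in Smo shRNA cells, all 32 of those tested, with the same count adjusted over the list alone and a median difference of 0.39 (camera adjusted p = 2.86e-15 over the 6 lists, adjusted p = 0.222 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, was 1.86-fold higher (0.90, adjusted p = 1.09e-08), Rrp12 1.72-fold (0.78, adjusted p = 5.5e-08) and Dkc1, the pseudouridine synthase dyskerin, 1.41-fold (0.49, adjusted p = 1.42e-07). Of 13 genes that host small nucleolar RNAs, 10 rose and 1 fell, with the same counts adjusted over the list alone and a median of 0.44 (camera adjusted p = 0.000204, adjusted p = 0.222 with an estimated correlation). Snhg3 was 2.16-fold higher (1.11, adjusted p = 2.23e-11) and Snhg10 2.25-fold (1.17, adjusted p = 2.54e-08), while Snhg18 was lower (-0.35, adjusted p = 0.000452).

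Of 20 Toll-like receptors and adaptors, 10 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.000202, adjusted p = 0.222 with an estimated correlation). Tlr1 was 4.38-fold lower (-2.13, adjusted p = 1.42e-09), Tlr3, a sensor of double-stranded RNA, 2.34-fold (-1.22, adjusted p = 5.76e-08) and the adaptor Myd88 1.22-fold (-0.28, adjusted p = 2.53e-05). That these 3 lists move as a whole is a hypothesis found and tested on the same arrays, and each call was lost with the estimated correlation.

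Retinoid genes held some of the largest decreases without a call for the list (camera adjusted p = 0.251), 7 of 29 being lower and 6 higher, with the same counts adjusted over the list alone. The median was 0.00 and the mean -0.26. Besides Aldh1a1 and Aldh1a7, the retinol dehydrogenase gene Adh1 was 4.78-fold lower (-2.26, adjusted p = 6.07e-11) and Dhrs3 3.66-fold lower (-1.87, adjusted p = 5.49e-10), while Rdh11 was 2.11-fold higher (1.08, adjusted p = 7.15e-10). Imprinted genes moved both ways (camera adjusted p = 0.48, median 0.02, mean -0.10), 6 of 26 lower and 4 higher, with the same counts adjusted over the list alone. Mest was 3.21-fold lower (-1.68, adjusted p = 1.85e-09), and the neighbours Sgce and Peg10 were 2.58-fold (1.37, adjusted p = 3.32e-09) and 2.13-fold higher (1.09, adjusted p = 1.93e-08). Of 16 EGF receptor ligands and receptors, 5 rose and 2 fell (6 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.251). Hbegf was 2.15-fold higher (1.11, adjusted p = 4.1e-08) and Tgfa 1.55-fold lower (-0.64, adjusted p = 4.06e-07).

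Granzyme genes that neighbour Mcpt8, named after their values were seen and not tested as a list, were higher too. Gzmd was 2.37-fold higher (adjusted p = 2.86e-08), Gzmf 1.85-fold (0.89, adjusted p = 2.92e-09) and Gzme 1.68-fold (0.75, adjusted p = 2.4e-07). Gzmg was 1.67-fold (adjusted p = 1.51e-05), Gzmn 1.61-fold (adjusted p = 1.00e-06) and Gzmc 1.14-fold higher (adjusted p = 0.0408). Ctsg, between Mcpt8 and these genes, was at 0.07 (adjusted p = 0.49). The granzyme genes are close paralogs and their probe sets can share signal.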
